A study of Arabidopsis thaliana with 36 samples.

How the data were processed

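RNA was sequenced from leaves of 5-week-old Arabidopsis plants of 4 genotypes: wild-type Col-0, the single mutant tpr1, the triple mutant tpr1 tpl tpr4 (called t3) and eds1-2. Leaves were infiltrated by syringe with Pseudomonas syringae pv. tomato carrying avrRps4 at an OD of 0.005 and taken immediately (0 h), at 8 h and at 24 h, with 3 replicates per genotype and time, which makes 36 libraries in 12 groups. Plants grew under 10 h of light at 22 °C. Polyadenylated RNA went into TruSeq libraries that were sequenced on 4 lanes, and 6 libraries list 2 runs. No mock-infiltrated leaves were sampled, so infection, infiltration and time of day cannot be separated in a comparison with 0 h. Time of day differs between 8 h and 0 h but not between 24 h and 0 h.

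The authors deposited 1 table of 20279 genes. Its read counts per gene are raw counts in the deposited table, whole numbers summing to between 18493058 and 26416327 per library, and only genes with at least 5 reads in at least 3 libraries are listed. The authors also deposited log2 CPM (counts per 1e6 reads), which differ from log2((count + 0.5) / (scaled total + 1) × 1e6) by 1 constant per library, with an SD of at most 2.9e-05. The deposited log2 fold changes set each mutant against Col-0 at the same time, and the deposited p-value columns are false discovery rates whose adjustment method is not stated. The processing notes name TopHat2, HTSeq, limma and TAIR10 without versions or roles. Whether reads were counted by strand is not stated. Gene names and positions came from a TAIR10.1 annotation by locus tag: 20133 loci were found and 146 were not.

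Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 20002 genes, TMM factors (0.769 to 1.18) scaled the libraries, and 1 quasi-likelihood model with 12 group means was fitted to all 36 libraries (24 residual degrees of freedom, prior degrees of freedom 3.87, common biological coefficient of variation 0.274). There were 20 comparisons, each two-sided: Col-0 at 8 h and at 24 h against 0 h, each mutant against Col-0 and t3 against tpr1 at each time, and the difference between each mutant's and Col-0's change from 0 h to 8 h or 24 h (an interaction term). P-values were adjusted by Benjamini and Hochberg over all genes tested within a comparison, and a gene is said to have risen, fallen or changed where its adjusted p from edgeR was under 0.05. Levels are CPM with TMM scaling, given as mean ± SD of 3 libraries, and log2 fold changes have standard errors (SE) from the model. Where a group had no reads, the fold is a bound against 3 counts over the group. Such bounds cover counting error only.

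Before the data were examined, the groups, the comparisons, the tests, the first alternatives to them, 25 gene lists (344 genes, 341 of them tested) and the rule for naming genes were fixed. The rule names the targeted genes, for each list up to 4 members with the smallest adjusted p (2 with the highest mean expression where none passed), and the 5 largest rises and 5 largest falls among genes that passed with a mean log2 CPM of at least 2 over all libraries and the same sign in all 3 same-numbered replicates. Any other gene is said to have been chosen after its values were seen. Genes ranked below as the largest rises or falls are the largest under this rule only. For each list, members that passed are counted over all genes tested and again adjusted over the list alone. The 22 lists with at least 4 members were also tested against all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The lists were targeted genes, TOPLESS family and EDS1 paralog, reported TPR1 target genes, salicylic acid, N-hydroxypipecolic acid, EDS1 partners and receptors, pattern-triggered immunity, camalexin and tryptophan, jasmonate synthesis, jasmonate response, ethylene and jasmonate defensins, photosynthesis, chlorophyll synthesis, senescence, early auxin response, abscisic acid, circadian clock, endoplasmic reticulum folding, aliphatic glucosinolates, flavonoids, and markers of guard cells, epidermis, phloem, xylem and dividing cells. The defensin list also holds genes that are not defensins, such as PR4 and CHIB.

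Replicates correlated on the log2 scale at 0.914 to 0.981, and no pair differed by as little as counting error alone would give (lowest chi-square per degree of freedom 11.26). Replicates thus spread beyond counting error. The source of this spread, and how far depth limited genes with few reads, was not tested. The median biological coefficient of variation was 0.234 over all libraries and 0.395 in Col-0 at 24 h. Replicate numbers were not treated as pairs, because changes in same-numbered replicates were hardly more alike (median correlation over genes 0.037, range -0.37 to 0.64) than in others (-0.015, -0.58 to 0.36). In 2 of 14 comparisons, t3 and eds1-2 against Col-0 at 0 h, every same-numbered pair was over 0.1 (0.28 to 0.32 and 0.27 to 0.46), and their counts are given with a replicate block as well. The first alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond 1 read, a filter of 5 CPM in 3 libraries, replicate number as a block, lane as a covariate, a model of the compared groups alone, and leaving out each library in turn. Alternatives chosen after the data were seen were scaling by total counts, the Benjamini-Yekutieli adjustment and leaving out the 3 Col-0 libraries numbered 2. The closing section gives their effect.

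The methods were tested on simulated counts for t3 against Col-0 at 24 h over 19913 genes: edgeR recovered 58 of 100 genes planted at a log2 change of 1 and 90 of 100 planted at 2, with 11 false calls among 159. The simulated Col-0 libraries had the spread estimated over all libraries (median biological coefficient of variation 0.234), not that of Col-0 at 24 h (0.395). Only genes above a minimum level were planted, so recovery in the real comparison may be lower. The authors' own fold changes and false discovery rates were used only for a side-by-side count. At a rate under 0.05 they list 135, 4320 and 3796 genes for eds1-2 at 0, 8 and 24 h, 20, 12 and 19 for tpr1 and 13, 12 and 11 for t3, and their log2 fold changes correlated with those of edgeR at 0.92 to 0.983 over genes. No library was left out of the reported values. Loci without reads in the table, such as genes under its read minimum, could not be tested.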

Results

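Each mutant carries lesions in the genes it is named for, so the RNA of those genes was measured first. EDS1 lies on chromosome 3 (17755329 to 17758147 in TAIR10.1), TPR1 and TPL on chromosome 1 (30260818 to 30267125 and 5414817 to 5421033) and TPR4 on chromosome 3 (5364081 to 5372293). In Col-0, EDS1 stood at 64.0 ± 16.7, 262 ± 104 and 82.1 ± 26.1 CPM at 0, 8 and 24 h. It stood at 6.85 ± 2.19, 4.97 ± 0.533 and 6.54 ± 1.14 CPM in eds1-2, with log2 changes of -3.22, -5.72 and -3.65 (adjusted p = 1.31e-06, 6.79e-11 and 2.92e-08, edgeR). TPR1 in tpr1 was lower by -1.42 at 8 h (23.0 ± 3.3 against 61.6 ± 16.9 CPM, adjusted p = 0.000142), while -0.59 at 0 h and -0.81 at 24 h did not pass (adjusted p = 0.0929 and 0.0704). Without Col-0 replicate 1 at 24 h, 1 targeted gene passed as lower in tpr1 at 24 h. TPR1 was the only targeted gene with a lower mean there (46.1 ± 4.32 against 81.0 ± 24 CPM). In t3, TPR4 fell to 9.30 ± 2.55, 4.70 ± 0.314 and 9.22 ± 0.617 CPM from 111.9 ± 5.03, 73.1 ± 1.29 and 122.4 ± 19.7 (log2 -3.59, -3.96 and -3.73). TPL fell by 1.69, 2.21 and 1.90 on the log2 scale (adjusted p = 0.00145, 2e-05 and 0.000252). TPR1 RNA in t3 did not differ detectably from Col-0 (log2 -0.19, -0.44 and -0.21, adjusted p = 0.897, 1 and 0.567). Over these genes, 40 of 45 values in mutant libraries lay below every Col-0 library of the same time, against 1 in 4 by chance for a single library set against 3. The 5 exceptions were all TPR1 in t3. The 2 other family members tested, TPR3 and TPR2, were higher in t3 at every time: TPR3 from 22.5 ± 6.95 to 127.5 ± 8.6 CPM at 0 h (adjusted p = 6.24e-06) and by 1.67 and 1.97 at 8 and 24 h, and TPR2 by 0.64, 0.72 and 0.75. EDS1B, a close copy of EDS1 whose reads may be shared with it, fell with EDS1 in eds1-2 (log2 -3.88 at 0 h, adjusted p = 0.000865).

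**Figure D1:**
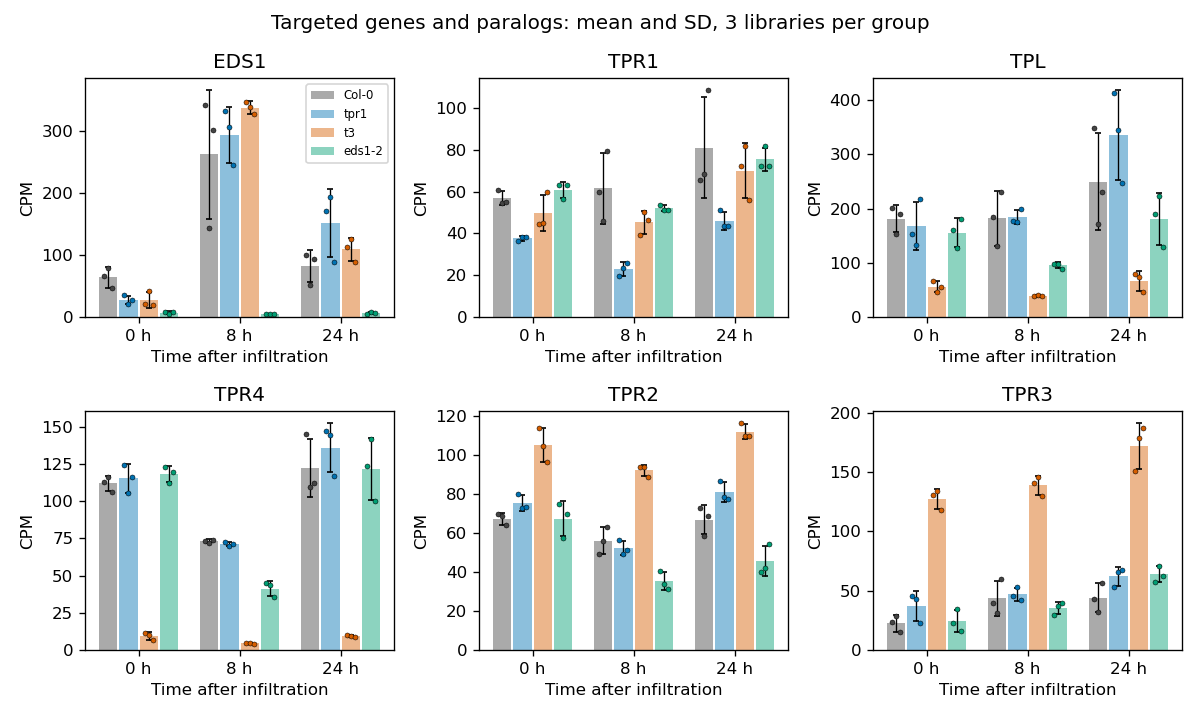
CPM (linear axes from 0) of EDS1, TPR1, TPL, TPR4, TPR2 and TPR3 by hours after infiltration and genotype, with bars for the mean and SD of 3 libraries and points for the libraries. EDS1 in eds1-2 averages 4.97 to 6.85 CPM and TPR4 in t3 4.70 to 9.30, below every Col-0 library of the same time, while TPR2 and TPR3 are higher in t3.

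PTAC17, the gene next to TPR1 on chromosome 1 (30258005 to 30260732), was lower in both mutants that carry a tpr1 allele. In t3 it fell by 8.49, 8.95 and 6.24 on the log2 scale at 0, 8 and 24 h, and in tpr1 by 2.16, 4.81 and 2.15 (0.203 ± 0.101 and 3.66 ± 0.651 CPM at 8 h against 103 ± 20 in Col-0, adjusted p = 3.83e-14 and 2.71e-10). AT1G80470, which overlaps the end of PTAC17, was read at 100.2 ± 2.71 CPM in tpr1 at 0 h against 0.0600 ± 0.104 in Col-0 and 0.0655 ± 0.0287 in t3. Strand use in counting is not stated, so reads at the overlap itself could belong to either gene. AT1G80470 shares only the stretch from 30258005 to 30258032 with PTAC17, which stood at 6.98 ± 1.43 CPM in tpr1 at 0 h. These values argue against shared reads as the source of the AT1G80470 level in tpr1.

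The largest differences among all libraries followed time. The first 3 principal components of log2 CPM held 48.6, 20.5 and 9.46 % of the variance, and the 0 h libraries lay apart from those of 8 and 24 h in the plot of components 1 and 2. In Col-0 the 58 photosynthesis genes took 24.1 ± 2.34 % of all counts at 0 h, 9.87 ± 2.72 % at 8 h and 13.5 ± 6.82 % at 24 h, and in eds1-2 at 8 h they took 15.9 ± 1.49 %. Col-0 replicate 2 stood apart after infection: its 20 salicylic acid genes lay at a median log2 of -1.32 and -1.37 below the other 2 Col-0 libraries at 8 and 24 h, and its photosynthesis genes 0.53 and 1.19 above them. Genes below given a fold that passed moved the same way in all 3 same-numbered replicates, except MAM3 in eds1-2 at 0 h and PR1, FMO1 and TOC1 in the last comparison of eds1-2.

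**Figure D2:**
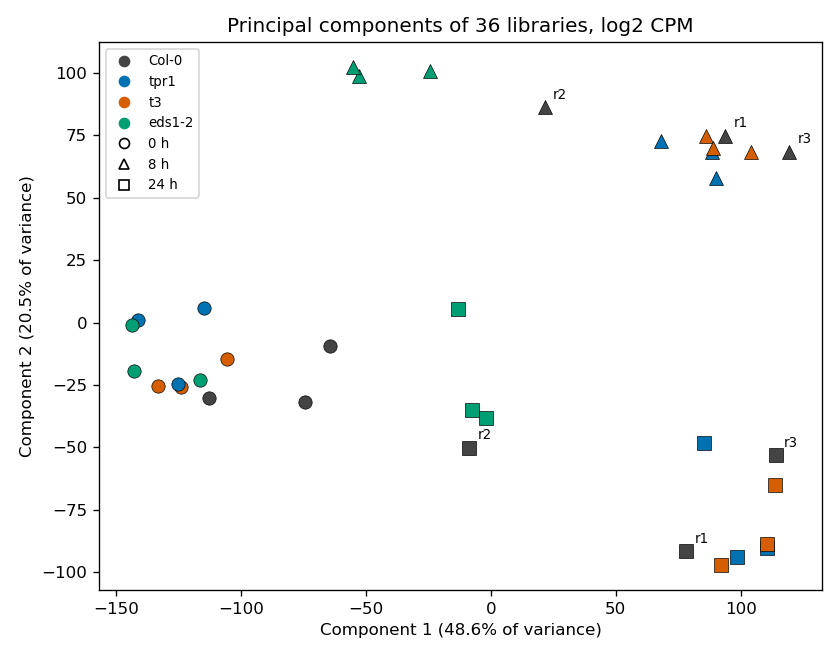
Principal components 1 and 2 of log2 CPM (48.6 and 20.5 % of the variance) for the 36 libraries, coloured by genotype and shaped by hours after infiltration, with the Col-0 replicates labelled at 8 and 24 h. At 8 and 24 h the eds1-2 libraries and Col-0 replicate 2 lie at lower values of component 1 than the other libraries.

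Which genes responded to infiltration in wild-type leaves was asked by setting Col-0 at 8 h against 0 h. RNA for salicylic acid synthesis rose: EDS5 went from 29.4 ± 9.79 to 614.5 ± 391 CPM (log2 4.38, SE 0.507, adjusted p = 1.46e-07, edgeR). ICS1, the enzyme gene that starts this route, went from 64.1 ± 11.7 to 338.9 ± 190 (2.40, adjusted p = 1.24e-05), and PBS3 rose by 3.76. PAD4, a partner of EDS1, rose from 40.3 ± 12.6 to 525 ± 280 CPM (log2 3.71), and EDS1 itself rose. Jasmonate genes rose as well, with AOC3 reaching 126 ± 77.2 CPM (4.97, adjusted p = 2.43e-08) and JAZ1 going from 12.3 ± 4.14 to 176.5 ± 107 (3.84). CYP94C1 and NAC019 were up by 5.06 and 5.83. Against these, LHCB2.1 fell by 3.81 (243 ± 86 against 3406 ± 233 CPM; near-identical copies share reads), RCA, which activates Rubisco, by 3.06 and GUN4, a chlorophyll synthesis gene, by 4.11. Of the 20002 genes tested, 10487 changed (6025 higher and 4462 lower, 6695 by at least 2-fold). Clock genes moved both ways (TOC1 rose by 4.22 and LUX by 5.44, while PRR9 fell by 6.52), and the time of day differed between these samples. The largest rises were in AT4G35160 (8.07), AT3G43250 (455 reads against 2), AT5G44570 (7.24), CYP82G1 (7.20) and AT4G36700, with 0 reads at 0 h and 96 at 8 h (at least 28.6-fold higher). Those that fell most were ASG4 (3 reads against 3420), AT4G27360 (2 against 1037), COL2 (-8.76), AT2G27420 (-8.72) and GBSS1 (-8.54).

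By list, genes that rose in Col-0 at 8 h were 14 of 20 for salicylic acid, 3 of 4 for N-hydroxypipecolic acid, 7 of 11 for EDS1 partners and receptors, and 21 of 28 for pattern-triggered immunity (CERK1 by 1.65, BAK1 by 2.01). The counts were 15 of 15 for camalexin and tryptophan (IGPS by 2.57), 11 of 13 for jasmonate synthesis and 20 of 21 for jasmonate response. Adjusted over the list alone, these 7 counts came out at the same numbers. Abscisic acid genes rose in 15 of 20 and fell in 2 (KIN1 rose by 5.04, COR15A by 3.51) and endoplasmic reticulum genes in 11 of 13 (12 adjusted over the list alone; BIP1 by 2.35). Photosynthesis genes fell in 55 of 58 (57 adjusted over the list alone), with 1 higher, and chlorophyll genes in 8 of 12, with 1 higher. Lower too were 8 of 16 early auxin genes (IAA17 by -2.94, 9 adjusted over the list alone; 2 higher), 6 of 15 for glucosinolates (MYB28 by -2.09) and 5 of 13 for flavonoids (F3H by -5.11; 1 higher). Of marker genes for cell types, lower were 5 of 7 for epidermis (TRY by -4.65), 4 of 8 for phloem, 3 of 6 for xylem and 2 of 7 for guard cells. Senescence genes went both ways (2 higher, 1 lower of 14), dividing cell genes too (3 and 2 of 8), and clock genes 8 and 6 of 16. No gene of the defensin list passed in edgeR, where PDF1.2A stood at 1.49 (adjusted p = 0.367) and PR4 at 0.19 (adjusted p = 0.759). Both reported TPR1 targets fell, CNGC2 by 1.93 and CNGC4 by 0.79 on the log2 scale (adjusted p = 0.000131 and 0.0117). The camera test passed for 12 of 22 lists with the preset correlation, but none did with an estimated correlation (smallest adjusted p = 0.275).

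**Figure D3:**
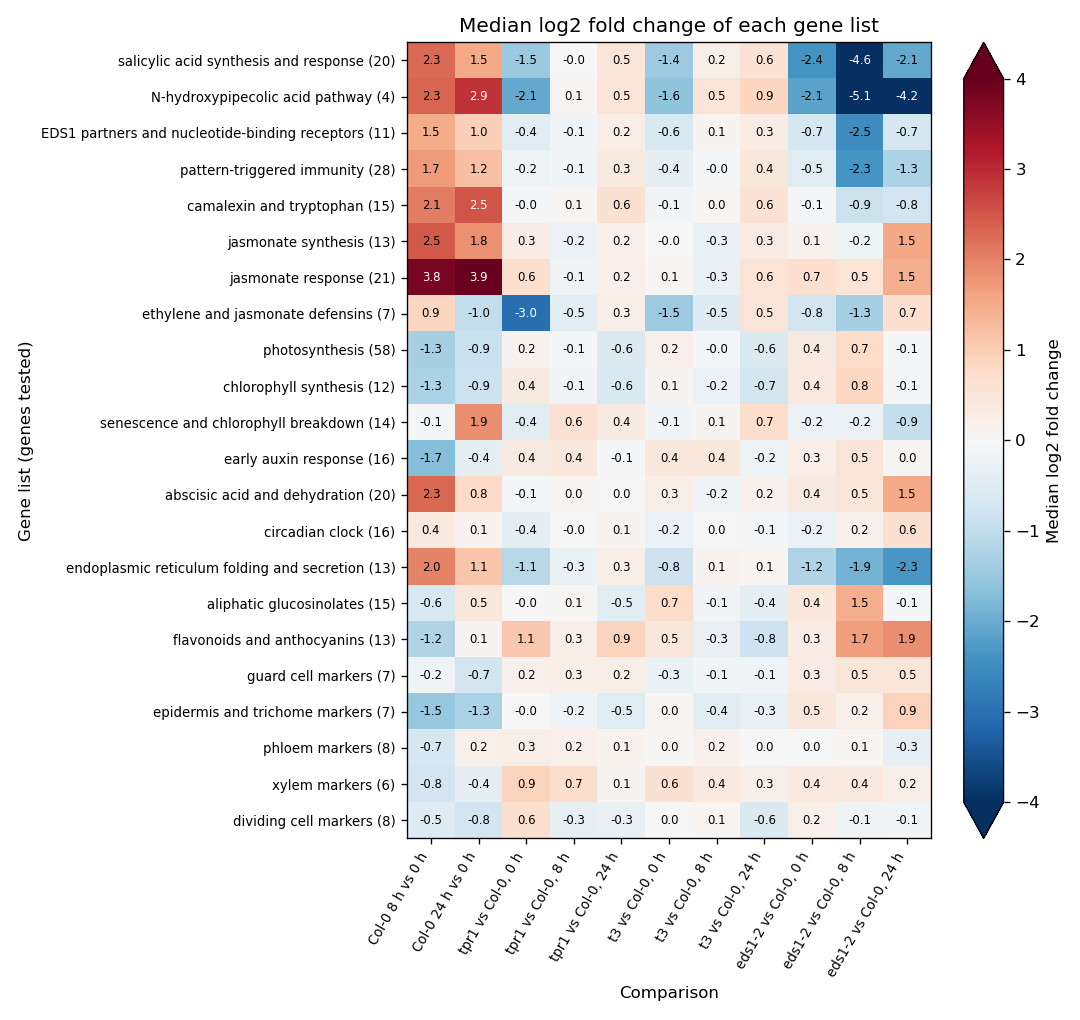
Median log2 fold change of the tested members of 22 gene lists (number in brackets) in Col-0 against 0 h and in each mutant against Col-0, with positive medians in red and negative in blue (colours end at 4 and -4). Salicylic acid and N-hydroxypipecolic acid medians are negative in eds1-2 at every time and in tpr1 and t3 at 0 h.

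At 24 h, when the time of day was that of 0 h, 7832 genes differed in Col-0 (4776 higher and 3056 lower, 4091 by at least 2-fold). ALD1 and FMO1, which make N-hydroxypipecolic acid, rose from 9.42 ± 2.9 to 296.4 ± 203 CPM (log2 4.97, SE 0.806, adjusted p = 4.6e-05) and from 10.7 ± 5.31 to 144.5 ± 75.9 (3.75, adjusted p = 0.00037). PBS3 was up by 3.75, PAD4 by 3.62, and BSMT1, a jasmonate-responsive methyltransferase gene, went from 0.403 ± 0.124 to 159.7 ± 166 CPM (8.61, adjusted p = 7.45e-07). SAG13, a marker of leaf ageing, rose from 37.5 ± 20 to 1679 ± 859 CPM (5.48). LHCB1.3 fell to 11760 ± 6590 from 29130 ± 5980 CPM (-1.31, adjusted p = 0.00224; copies share reads). Genes that had 0 reads at 0 h reached 35.0 ± 35.4 CPM (DIN2, at least 809-fold higher), 31.4 ± 16 (OSM34, 726-fold) and 28.0 ± 13.4 (UPI, 646-fold). DXPS1 reached 42.9 ± 41.1 CPM from 2 reads. The largest falls were in MYB111 (-3.14), GASA6 (-3.10), AT5G45670 (-2.68), EXPA8 (-2.58) and EXPA1 (-2.53), the last of these a gene for a protein that loosens cell walls. Leaving out Col-0 replicate 1 at 24 h gave 4969 genes, replicate 3 at 24 h 3900 and replicate 3 at 0 h 4895.

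Lists at 24 h showed 13 of 20 salicylic acid genes higher, 3 of 4 for N-hydroxypipecolic acid (4 adjusted over the list alone), 6 of 11 for EDS1 partners and 18 of 28 for pattern-triggered immunity (19 adjusted over the list alone). They showed 15 of 15 for camalexin (ASA1 by 3.12), 11 of 13 for jasmonate synthesis, 21 of 21 for jasmonate response and 3 of 7 for the defensin list (CHIB by 3.89). In addition, 10 of 14 senescence genes (NYE2 by 4.12) and 9 of 20 abscisic acid genes (HAI1 by 5.53; 1 lower) rose. Photosynthesis genes fell in 39 of 58 (52 adjusted over the list alone), chlorophyll genes in 6 of 12, guard cell genes in 5 of 7 (1 higher), epidermis genes in 5 of 7, phloem genes in 3 of 8 (1 higher) and dividing cell genes in 2 of 8. Of the rest, auxin genes went both ways (4 higher, GH3.6 by 4.71, and 3 lower), and 5 clock genes, 4 flavonoid genes (PAP1 by 2.83), 3 glucosinolate genes (1 lower) and 1 endoplasmic reticulum gene were higher. With the preset correlation 13 of 22 lists passed, and with an estimated correlation none (smallest adjusted p = 0.0929, for camalexin and for jasmonate response).

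Whether leaves without EDS1 differ at infiltration was asked by comparing eds1-2 with Col-0 at 0 h. Salicylic acid genes were already low: WRKY54 stood at 1.99 ± 1.66 against 29.2 ± 7.7 CPM (log2 -3.87, SE 0.519, adjusted p = 2.98e-05, edgeR), WRKY70 was lower by -2.80 (adjusted p = 0.000616) and SARD1 by -3.96. WAK1, a cell-wall receptor kinase gene, stood at 32.4 ± 24.3 against 290 ± 142 CPM (-3.16), PAD4 at a log2 of -2.18 (adjusted p = 0.0261), GSTF6 at -2.30 and PR4 at -2.70. Some genes of other routes moved: COR15A was higher by 1.28, JAZ9 by 1.07, and MAM3, of glucosinolate synthesis, had 2 reads against 318. In all, 483 genes changed (55 higher, 428 lower; 25 and 574 with scaling by total counts; 498 in all with a replicate block), among them 13 of 20 for salicylic acid (17 adjusted over the list alone), 2 of 4 for N-hydroxypipecolic acid (3), and 3 of 11 for EDS1 partners (6), all lower. Lower too were 7 of 28 for pattern-triggered immunity (8) and 2 of 13 for endoplasmic reticulum folding (3), and 4 of 20 for abscisic acid were higher. With an estimated correlation camera still passed for salicylic acid (adjusted p = 0.0153) and N-hydroxypipecolic acid (adjusted p = 0.0236), and for no other list. AT3G44740, 1 of several strongly lowered genes on the chromosome of EDS1, had 0 reads against 7.12 ± 0.507 CPM (at least 150-fold lower). AT3G44430 fell by 7.44 and AT3G47675 by 6.60. Under the naming rule the highest rises were SADHU3-2 (4.11), KTI1 (3.36), AT1G14250 (2.41), AT4G29700 (2.36) and AT1G73325 (2.33). AT3G31023 (8.87) and AT3G44070 (7.62), chosen after their values were seen, rose more but lay below its expression limit. The count became 292 and 252 without Col-0 replicates 1 and 2, and 209 and 274 without eds1-2 replicates 2 and 3.

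At 8 h the same comparison asked which genes differed between eds1-2 and Col-0 after infection. It does not set apart differences already present at 0 h, which the interaction terms below do. PAD4, HR4 and AT3G43690, named here, lie within 3 Mb of EDS1, where strain variants may also lower reads. ICS1 stood at 10.9 ± 3.05 CPM in eds1-2 against 338.9 ± 190 (log2 -4.96, SE 0.432, adjusted p = 2.53e-09), PAD4 at 9.01 ± 1.72 against 525 ± 280 (-5.86, adjusted p = 8.72e-08). PBS3, EDS5 and FMO1 were lower by -6.03, -5.20 and -4.88. HR4, a homolog of the RPW8 resistance proteins, had 5.81 ± 2.84 CPM against 1549 ± 825 (-8.06). The photosynthesis gene LHCB1.3 was higher than in Col-0 by 1.11 (adjusted p = 0.00637), the chlorophyll gene GUN4 by 1.27, and the flavonoid gene CHS was higher by 2.79 (adjusted p = 0.00173). CNGC2 and CNGC4 were higher by 1.32 and 1.01 (154.2 ± 9.03 against 61.6 ± 44.5 and 80.8 ± 10.3 against 40.2 ± 14.9 CPM). Among the corepressor genes, TPL, TPR4 and TPR2 were lower by -0.94, -0.82 and -0.67. Counting all genes, 7658 changed (3515 higher and 4143 lower, 1591 and 2747 of them by at least 2-fold), or 4973 without Col-0 replicate 3. Lower were 19 of 20 for salicylic acid, 4 of 4 for N-hydroxypipecolic acid, 10 of 11 for EDS1 partners (11 adjusted over the list alone), and 25 of 28 for pattern-triggered immunity (26). So were 10 of 13 for endoplasmic reticulum folding (12) and 10 of 15 for camalexin (PAD3 by -5.18, with 2 higher). Higher were 27 of 58 for photosynthesis (34 adjusted over the list alone), 7 of 12 for chlorophyll, 10 of 15 for glucosinolates (11; SOT18 by 1.74), 8 of 13 for flavonoids and 9 of 20 for abscisic acid (3 lower). None of the 10 lists past the preset camera test passed with an estimated correlation (smallest adjusted p = 0.105). Others that fell far were AT3G60470 (1 read against 1261), AT3G43690 (1 against 673) and AT5G41280 (2 against 700). Under the naming rule SADHU3-2 (4.65), AT2G22200 (4.23) and AT3G61920 (3.77) rose most. AT3G44070 (11.68), chosen after its values were seen, rose more but lay below the rule's expression limit.

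By 24 h, 6670 genes differed between eds1-2 and Col-0 (2862 higher and 3808 lower, 1534 and 2204 by at least 2-fold). With DESeq2's size factors the numbers were 3297 higher and 3378 lower, so the size of the excess of falls depends on scaling. ALD1 stood at 2.57 ± 0.974 CPM in eds1-2 against 296.4 ± 203 (log2 -6.85, SE 0.891, adjusted p = 1.45e-06), FMO1 at -6.14 and the ageing marker SAG13 at -5.82 (adjusted p = 1.55e-05). Jasmonate genes were higher: OPR3 had 738.9 ± 77.1 against 138.9 ± 91 CPM (2.41, adjusted p = 5.35e-05), and JAZ2 and JAZ3 were up by 1.91 and 1.99. COR15B, a dehydration gene, had 279.6 ± 48.2 against 15.5 ± 5.32 CPM (4.18, adjusted p = 2.61e-08). The largest rises included ILL5, of the family that frees auxin from conjugates (1194 ± 102 against 1.35 ± 1.87 CPM, 9.77, adjusted p = 2.12e-09), and the expansin gene EXPA10 (1157 ± 222 against 14.7 ± 6.15, 6.30). Under the naming rule ASN1 (-9.24) and AT1G33950 (-8.50) fell furthest beside AT2G01422 (1 read against 1048) and AT5G46960 (2 against 1494). AT1G80470, at 0 reads, also passed (at least 127-fold lower), but that call rested on Col-0 replicate 1 alone, at 17.1 CPM. List counts lower were 14 of 20 for salicylic acid (15 adjusted over the list alone; 1 higher), 3 of 4 for N-hydroxypipecolic acid, 7 of 11 for EDS1 partners and 14 of 28 for pattern-triggered immunity (17; 2 higher). Also lower were 9 of 15 for camalexin (10; 2 higher), 12 of 13 for endoplasmic reticulum folding (13; CRT3 by -2.61) and 5 of 14 for senescence (1 higher). Those higher were 10 of 13 for jasmonate synthesis, 12 of 21 for jasmonate response (13; 1 lower), 15 of 20 for abscisic acid (16), 5 of 16 for the clock (6; ELF3 by 2.49) and 7 of 13 for flavonoids (DFR by 4.58). The smallest adjusted p with an estimated correlation was 0.339.

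**Figure D4:**
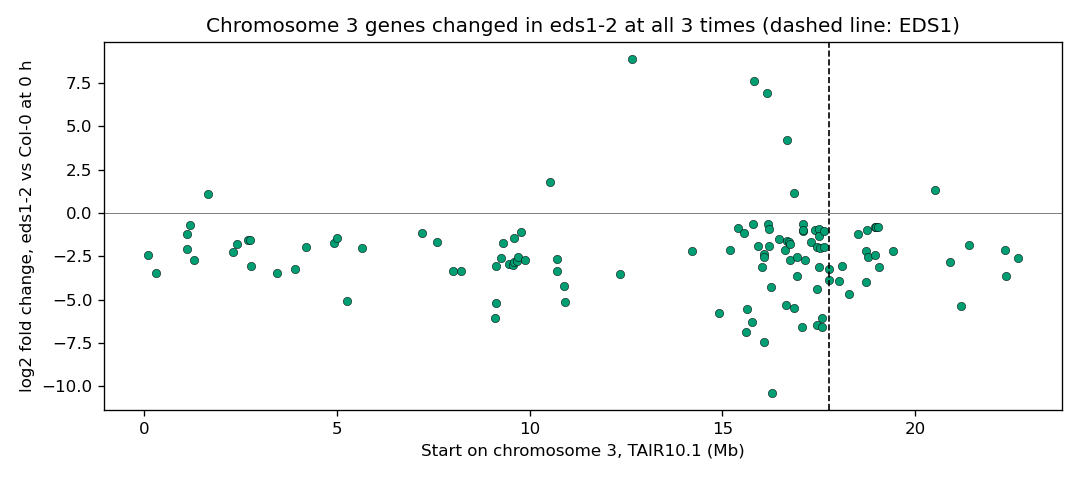
Log2 fold change in eds1-2 against Col-0 at 0 h of the genes on chromosome 3 that changed at all 3 times (points), by start position in Mb, with EDS1 at the dashed line. Of 382 such genes on all chromosomes, 67 lie within 3 Mb of EDS1.

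What the tpr1 lesion changes was asked in tpr1 against Col-0. PTAC17 and AT1G80470, near TPR1, changed in tpr1 as well, so differences cannot be assigned to TPR1 alone. At 0 h 449 genes differed (95 higher, 354 lower). Among those that fell were ICS1 at 22.8 ± 5.44 against 64.1 ± 11.7 CPM (log2 -1.49, adjusted p = 0.0326, edgeR), PR5 at -2.14 (adjusted p = 0.0217) and PR2 at -5.10 (412.5 ± 370 CPM in Col-0, adjusted p = 0.0323). PR4 stood at -3.11 (adjusted p = 0.0027), GSTF6 at -2.46 and FMO1 at -3.13. LDOX and DFR, of anthocyanin synthesis, were higher by 4.87 and 4.72. So was CESA4, a secondary-wall cellulose synthase gene. The strongest falls and rises included AT3G55920 (0.314 ± 0.315 against 10.4 ± 0.883 CPM, -5.03, adjusted p = 4.99e-09) and SADHU3-2 (40.5 ± 5.72 against 0.446 ± 0.284, 6.51). Both stood near the Col-0 level in t3 at 0 h (11.3 ± 1.11 and 0.374 ± 0.449 CPM). Whether they follow the tpr1 lesion or another trait of the tpr1 line was not tested. MATK, a plastid gene, at 85.8 ± 128 CPM followed 1 library (tpr1 replicate 2, with 1.51 % chloroplast counts). Lists lower were salicylic acid with 5 of 20 (11 adjusted over the list alone), N-hydroxypipecolic acid with 2 of 4 (3), the defensin list with 1 of 7 (4) and endoplasmic reticulum folding with 2 of 13 (3), and xylem genes were higher in 1 of 6 (6 adjusted over the list alone). With an estimated correlation the smallest adjusted p was 0.177. The 449 genes became 92, 69 and 752 without Col-0 replicates 1, 2 and 3, 246 and 51 without tpr1 replicates 1 and 2, and 267 without every Col-0 library numbered 2.

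After infection few genes set tpr1 apart from Col-0: 23 at 8 h (4 higher, 19 lower) and 32 at 24 h (3 higher, 29 lower), with 623 and 1953 at an unadjusted p under 0.05. At 8 h AT3G55920 stood at 0.119 ± 0.0557 against 16.5 ± 2.61 CPM (log2 -7.05, adjusted p = 1.17e-11), AT1G25430 at -4.65 and AT5G35480 at -3.24. QQS, which affects starch content, rose by 3.38 (23.9 ± 1.05 against 2.29 ± 0.897 CPM, adjusted p = 0.00178) and SADHU3-2 by 6.87. At 24 h AT1G25430 was lower by -5.27, AT5G35480 by -3.74 and AT3G15310 by -3.73. QQS (2.68), AT1G22550 (1.60) and ABH1, a cap-binding protein gene (0.82, adjusted p = 0.0011), were the 3 that rose. AT2G01422 was almost unread in tpr1, with 1 read at each time against 2760 and 1048. Apart from TPR1 at 8 h, no list had a member past all-gene adjustment at 8 or 24 h. Adjusted over the list alone 4 of 16 auxin genes were higher at 8 h (adjusted p = 0.0868 with an estimated correlation). At 24 h the count became 63 and 473 without Col-0 replicates 1 and 3 and 21, 19 and 52 without tpr1 replicates 1, 2 and 3.

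The triple mutant t3 was compared with Col-0 to ask what the lesions it is named for do, with the limit that TPR1 RNA was not detectably lower in it. PTAC17, next to TPR1, was almost unread in t3 (0.0808 ± 0.025 CPM at 0 h). Differences can therefore not be assigned to the named genes alone. At 0 h 61 genes differed (23 higher, 38 lower; 13 and 68 with scaling by total counts; 81 in all with a replicate block), with CBP60g, a regulator of salicylic acid synthesis, at 7.31 ± 1.52 against 48.3 ± 10.7 CPM (log2 -2.72, adjusted p = 0.00381, edgeR) and ICS1 lower by -1.75 (adjusted p = 0.0321). CER1, of wax synthesis, rose by 3.48, COR15A by 1.56 and the glucosinolate gene FMOGS-OX1 by 1.07. CSLA01, a mannan synthase family gene, stood at 108.7 ± 11.2 against 1.29 ± 1.3 CPM (6.34, adjusted p = 0.00199). QQS was higher by 3.27 and AT1G73325 by 2.47. MRD1 (-4.92), RLP7 (-4.01) and CML37 (-3.86) were among the largest falls. Salicylic acid genes were lower in 2 of 20 (8 adjusted over the list alone). Adjusted in that way, 2 of 4 N-hydroxypipecolic acid genes, 4 of 11 EDS1 partners and 6 of 28 pattern-triggered immunity genes were lower and 7 of 15 glucosinolate genes higher. With an estimated correlation no list passed (smallest adjusted p = 0.15). Without Col-0 replicates 1, 2 and 3 the count was 24, 25 and 96, and without t3 replicates 1, 2 and 3 it was 22, 192 and 14.

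In infected t3 leaves 14 genes differed from Col-0 at 8 h (8 higher, 6 lower) and 21 at 24 h (10 higher, 11 lower), with 912 and 2969 at an unadjusted p under 0.05. QQS was higher by 3.16 and 2.72 (20.5 ± 2.71 against 2.29 ± 0.897 CPM at 8 h, adjusted p = 0.00452), AT2G34655 by 1.83 and 1.35, and AT2G25420 by 1.18 and 1.14. MRD1 was lower by -7.74 and -6.19 (0.110 ± 0.0531 against 24.5 ± 3.29 CPM at 8 h, adjusted p = 1.11e-05). AT2G01422 had 0 reads in t3 at 24 h against 14.3 ± 6.95 CPM (at least 352-fold lower), and TBL38 rose by 1.64. The call on AT1G80470 (1 read against 429) rested on Col-0 replicate 1 alone. Outside the targeted genes and their family no list had a member past all-gene adjustment, and over the list alone 6 of 12 chlorophyll genes were lower at 24 h (adjusted p = 0.534 with an estimated correlation). At 8 h the count was 8 without Col-0 replicate 1. At 24 h it was 37, 11 and 1324 without Col-0 replicates 1, 2 and 3, 10 and 13 without t3 replicates 1 and 2, and 12 without every Col-0 library numbered 2.

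Setting t3 against tpr1 asked how these lines differ, with 270 genes changed at 0 h (134 higher, 136 lower), 45 at 8 h (34 and 11) and 47 at 24 h (33 and 14). Besides the tpl and tpr4 lesions, the lines differed in RNA next to TPR1. At 0 h AT1G80470 stood at 100.2 ± 2.71 CPM in tpr1 and 0.0655 ± 0.0287 in t3, and PTAC17 at 6.98 ± 1.43 and 0.0808 ± 0.025. The changes can therefore not be assigned to the tpl and tpr4 lesions alone. TPR4 was lower by -3.63, -3.92 and -3.88, TPL by -1.58, -2.23 and -2.33, and TPR3 higher by 1.78, 1.57 and 1.47. TPR1 itself was higher in t3 than in tpr1 at 8 h by 0.98 (adjusted p = 0.00789, edgeR). At 0 h WRKY40 was lower in t3 by -4.19 (adjusted p = 0.00139), PUB22 by -3.74 and WRKY33 by -2.11, and 4 of 28 pattern-triggered immunity genes were lower (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.794 with an estimated correlation). JAZ1 was lower by -2.11 and CBP60g by -1.90 (adjusted p = 0.0275). The glucosinolate gene CYP79F1 stood at 156.4 ± 33.4 against 18.9 ± 5.22 CPM (3.05, adjusted p = 0.00206), and 2 of 15 members were higher (11 adjusted over the list alone, adjusted p = 0.276 with an estimated correlation). AT3G55920 (5.15 and 7.32 at 0 and 8 h), AT1G25430 (5.09, 5.54 and 5.86) and AT5G35480 (3.13 and 3.34 at 8 and 24 h) were higher in t3, with AT3G55920 at 11.3 ± 1.11 CPM at 0 h against 10.4 ± 0.883 in Col-0. SADHU3-2 was lower by -6.73, -8.51 and -6.66. At 24 h 6 of 13 flavonoid genes were lower, adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). Of the 7 guard cell markers, SCAP1 was lower at 0 h (-0.96, adjusted p = 0.0436). Adjusted over the list alone 3 were lower at 0 h and 2 at 24 h, with preset camera adjusted p = 0.000545, 0.00256 and 0.000253 at 0, 8 and 24 h but 0.276, 0.504 and 0.159 with an estimated correlation. At 0 h the count was 166 and 172 without tpr1 replicates 1 and 2 and 103 and 89 without t3 replicates 1 and 3, and at 24 h it was 31 without tpr1 replicate 1.

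Whether a mutant's change from 0 h differed from that of Col-0 was tested with interaction terms. In eds1-2, 1632 genes differed in their change to 8 h (426 higher, 1206 lower). PBS3 differed by -4.79 (adjusted p = 0.000195, edgeR), ICS1 by -3.57 (adjusted p = 0.000222), EDS5 by -3.80 and PAD4 by -3.69 (adjusted p = 0.00407), and CERK1, the chitin receptor, by -1.69 (adjusted p = 7e-04). Differences ran furthest down in PP2-A6 (-7.77, adjusted p = 3.9e-05), RSH4 (-7.02) and CHX17 (-6.20) and furthest up in AT4G33980 (5.07) and AT3G61920 (4.23). Lists lower were 5 of 20 for salicylic acid (7 adjusted over the list alone), 2 of 4 for N-hydroxypipecolic acid (3), 7 of 11 for EDS1 partners (10) and 10 of 28 for pattern-triggered immunity (15), and the smallest adjusted p with an estimated correlation was 0.294. The count was 915, 3634 and 748 without Col-0 replicates 1, 2 and 3 at 8 h, and 1019 without Col-0 replicate 3 at 0 h. It was 967 without eds1-2 replicate 1 at 0 h, 942 without eds1-2 replicate 2 at 8 h and 4564 without every Col-0 library numbered 2.

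For the change to 24 h, 1863 genes differed in eds1-2 (1008 higher, 855 lower; 1328 and 638 with DESeq2's size factors, 1235 and 460 with total counts, so the balance of directions depends on scaling). ALD1 differed by -5.38 (adjusted p = 0.00165, edgeR), PR1, a salicylic acid marker, by -5.98 (adjusted p = 0.0174), SAG13 by -5.39 and FMO1 by -3.76 (adjusted p = 0.0215). WRKY54, low at 0 h, differed by 2.63 and WRKY40 by 4.26. Among the 5 clock genes that passed, the difference was 2.86 for ELF3 (adjusted p = 0.000198), 3.66 for LUX and 1.61 for TOC1. ELF3 itself was at -0.37 in eds1-2 against Col-0 at 0 h (adjusted p = 0.857) and at 2.49 at 24 h. Upward differences were also seen in COR15B (3.77), OPR3 (2.02) and LOX3 (1.83). Outermost were DIN2 (-11.45), DXPS1 (-10.77), KTI1 (-10.73, adjusted p = 1.57e-06) and UPI (-10.19), fitted values that rest on few or no reads in 1 group and are no bounds, and ILL5 (8.74, adjusted p = 1.27e-05) and AT4G33980 (7.38). Upward were 5 of 16 clock genes, 3 of 13 jasmonate synthesis genes (8 adjusted over the list alone) and 3 of 20 abscisic acid genes, and the smallest adjusted p with an estimated correlation was 0.371. Without eds1-2 replicate 1 at 0 h the count was 1211, and without eds1-2 replicate 1 at 24 h it was 1136.

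In tpr1 the change to 24 h differed from Col-0 for 191 genes (139 higher, 52 lower; 163 and 34 with total counts). They included EDS1 (2.07, adjusted p = 0.0333, edgeR), ICS1 (2.15, adjusted p = 0.0457), FMO1 (4.09, adjusted p = 0.0482), PR4 (3.55), GSTF6 (3.08) and ORE1, a senescence regulator (5.32). Also among them were the receptor-like genes RLP41 (5.44), RLP11 (5.36) and RLP7 (5.13). Of these, ICS1, FMO1, PR4, GSTF6 and ORE1 were lower than in Col-0 at 0 h and passed in neither direction at 24 h. Salicylic acid genes were higher in 1 of 20 (14 adjusted over the list alone), N-hydroxypipecolic acid genes in 2 of 4 (3) and endoplasmic reticulum genes in 2 of 13 (3), with adjusted p = 0.327 or more for every list with an estimated correlation. The 191 genes became 0, 0 and 754 without Col-0 replicates 1, 2 and 3 at 0 h, 842, 4 and 2267 without Col-0 replicates 1, 2 and 3 at 24 h, and 1 and 686 without tpr1 replicates 2 and 3 at 0 h. It became 0, 3 and 985 without tpr1 replicates 1, 2 and 3 at 24 h, and 0 without every Col-0 library numbered 2 (where edgeR gave 2220 at an unadjusted p under 0.05). For the change to 8 h only 5 genes differed in tpr1 (3 higher, 2 lower; 1497 at an unadjusted p under 0.05), with PTAC17 at -2.65 (adjusted p = 0.0176) and AAP2, an amino acid permease gene, at 3.70 (adjusted p = 0.0441). The other 3, chosen after their values were seen, were ORA47 (-5.80), GLR2.9 (4.17) and AT2G44380 (3.59). That count was 28 and 3 without Col-0 replicate 3 and tpr1 replicate 1 at 0 h, 0 or 1 without 9 of the other libraries (Col-0 replicates 1 and 2 and tpr1 replicates 2 and 3 at 0 h, Col-0 replicates 1, 2 and 3 and tpr1 replicates 2 and 3 at 8 h), and 3 without every Col-0 library numbered 2.

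For t3 edgeR found 0 genes whose change to 8 h or to 24 h differed from Col-0, with 1131 and 3019 at an unadjusted p under 0.05. DESeq2 found 8 and 153, and limma-voom 0 and 0. Adjusted over the list alone, 5 and 11 of 20 salicylic acid genes differed upward at 8 and 24 h, as did 2 of 4 N-hydroxypipecolic acid genes at each time and 5 of 11 EDS1 partners at 24 h (adjusted p = 0.13 at 8 h and 0.236 at 24 h at the smallest with an estimated correlation). Without t3 replicate 2 at 0 h the counts were 3 and 108. The count for 24 h was 2 without Col-0 replicate 3 at 0 h, 714 without Col-0 replicate 3 at 24 h and 1 without every Col-0 library numbered 2.

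Whether t3 and tpr1 act on genes that are low in eds1-2 was tested on the 2747 genes that were at least 2-fold lower in eds1-2 at 8 h, a set chosen on libraries of the same series. They are called EDS1-dependent, but may include genes already low at 0 h or affected by strain variants near EDS1. At 24 h their mean log2 fold change was 0.314 in t3 (-0.110 for the other genes; 2301 of the set above 0) and 0.266 in tpr1 (2352 above 0), with camera p = 5.96e-14 and 7.64e-15 at the preset correlation but 0.172 and 0.158 with an estimated correlation. Without Col-0 replicate 2 at 24 h the means were 0.0708 and 0.0195, and without Col-0 replicate 3 at 24 h they were 0.534 and 0.486. Without every Col-0 library numbered 2 they were 0.0773 and 0.0145. ICS1, PAD4 and PBS3 belong to this set, and none of them passed in t3 or tpr1 at 24 h.

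Effects of t3 and tpr1 share the same Col-0 libraries, so their correlation over genes was set against simulations that share only those. At 24 h it was 0.626 over the 20002 genes, which are not independent replicates, against 0.629 in 40 simulations (0.611 to 0.649), and the covariance was 0.227 against 0.171 (0.161 to 0.179). The simulations drew each gene independently, while genes in the real libraries varied together. Their ranges are therefore too narrow to decide whether an effect is shared beyond the Col-0 libraries. Without Col-0 replicates 1, 2 and 3 at 24 h the covariance was 0.387, 0.15 and 0.449. The simulations hold every mutant at the Col-0 level, while 6670 genes changed in eds1-2 at 24 h. Such changes by themselves lower a correlation, so its distance from the simulated value for eds1-2 says nothing about t3. Between t3 and eds1-2 the correlation was -0.026 against 0.624 and the covariance -0.021 against 0.171. The sign of both rests on single libraries: the correlation was 0.065, 0.114 and 0.107 without Col-0 replicates 1, 2 and 3, 0.009 without t3 replicate 3 and 0.035 without eds1-2 replicate 3, and the covariance 0.062, 0.088, 0.111, 0.009 and 0.031. The genes that changed in both t3 and tpr1 in the same direction numbered 4 at 24 h against 0.025 on average in simulations, but 352 without Col-0 replicate 3 and 2 without t3 replicate 2. At 0 h, 203 genes changed in both tpr1 and eds1-2, 202 of them in the same direction, and t3 shared 20 with tpr1 and 33 with eds1-2 (20 and 32 in the same direction).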

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

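The tests of the Col-0 library patterns and of gene positions, with their marker rules and windows, and the counts over other splits of the libraries were chosen only after the results were seen. Interaction terms showed that the change from 0 h differed between mutants and Col-0 for 5 genes (8 h) and 191 genes (24 h) in tpr1 and for 1632 (8 h) and 1863 (24 h) in eds1-2. ICS1 and FMO1 were among the 191 in tpr1, in the direction of a larger rise, and ICS1 among the 1632 in eds1-2, in the direction of a smaller one. Leaving out single libraries took the 5 to between 0 (Col-0 replicate 1 at 0 h) and 28 (Col-0 replicate 3 at 0 h), the 191 to between 0 (Col-0 replicate 1 at 0 h) and 2267 (Col-0 replicate 3 at 24 h), the 1632 to between 748 (Col-0 replicate 3 at 8 h) and 3634 (Col-0 replicate 2 at 8 h) and the 1863 to as few as 1136 (eds1-2 replicate 1 at 24 h). Every other library that moved a count by over 1.5 times is given with the interaction terms in the report. Among 21 regroupings of the same libraries, the real one included, 3 gave at least 5 genes (highest 146), 4 at least 191 (highest 922), 3 at least 1632 (highest 6240) and 3 at least 1863 (highest 4823), so chance was not excluded for any of the 4 counts. Regrouping within each time carries the difference between genotypes at that time into the term, so the highest of these counts may come from genotype itself. For t3 the real count was 0 at 8 h and at 24 h, which all 21 regroupings reach by construction (highest 58 and 329), so they say nothing about chance. There edgeR had 1131 and 3019 genes at an unadjusted p under 0.05, DESeq2 8 and 153 and limma-voom 0 and 0.

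Col-0 replicate 1 at 24 h held reads of 2 genes that were high in tpr1 and low in other Col-0 libraries. AT1G80470 stood at 17.1 CPM (at most 0.18 in any other Col-0 library, 28.1 to 36.2 in tpr1 at 24 h) and SADHU3-2 at 6.08 CPM (at most 1.28, and 19.4 to 27.6). SADHU3-2 was also read in eds1-2 (5.70 ± 3.42 CPM at 24 h), so it does not mark tpr1 alone. An exchange of the whole library with a tpr1 library was excluded by AT3G55920, which had 6.52 CPM in that library and at most 0.673 in any tpr1 library. RNA or tissue of tpr1 mixed into the library may explain these reads, with a lowest share of the tpr1 level of 0.247 over the 2 genes that qualified (the other at 0.546), but looser marker rules gave 3 genes with shares from 0.135, below the 0.152 seen in another Col-0 library, so the tables cannot decide. No biological explanation was tested. The calls on AT1G80470 in eds1-2 and t3 at 24 h rest on this library. So does its call in Col-0 at 24 h against 0 h (log2 6.51, adjusted p = 0.00103, edgeR). RNA of tpr1 in this library would shrink differences between tpr1 and Col-0 at 24 h. Without the library, 1 targeted gene passed as lower in tpr1 at 24 h, against 0 with it.

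Col-0 replicate 2 responded less than the other Col-0 libraries: its 20 salicylic acid genes lay at a median log2 of -1.32 at 8 h and -1.37 at 24 h below them, and photosynthesis genes 0.53 and 1.19 above. RNA of eds1-2 in those libraries was argued against by 3 genes read only in eds1-2, whose median share was 0 (highest 0.02), where 0.736 and 0.742 would be needed. RNA of 0 h leaves in the 8 h library was argued against by 5 clock genes low at 8 h, whose highest share of the 0 h level was 0 (0.014 over 6 genes with a looser rule), where 0.779 would be needed. An effect of the lane alike on all its libraries was argued against at 24 h, where photosynthesis genes in its other libraries lay at -0.43 (t3) and -0.31 (eds1-2) against the rest of their groups, but at 8 h its only other library, of eds1-2, lay at 0.16, which cannot decide. A lower dose and a slower response of those plants were not tested, remain open and could each lower EDS1, which stood at 144 CPM in this library at 8 h against 341 and 301.

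Of 382 genes changed in eds1-2 at all 3 times, all in a constant direction, 67 (17.5 %) lay within 3 Mb of EDS1 on chromosome 3, against 955 of the 20002 tested genes (4.77 %; odds ratio 4.49, Fisher's exact test, two-sided, p = 1.24e-20). Windows of 1, 2, 5 and 8 Mb gave odds ratios of 4.86, 5.54, 3.29 and 2.85. Loss of EDS1 activity alone, if it acts evenly wherever genes lie, was argued against by the odds ratio of 4.49. It was not excluded, because the test takes genes as independent. The 67 include EDS1 and EDS1B themselves and neighbours such as HR3 and HR4, and clustering of genes that need EDS1 was not tested. Strain variants near EDS1 may account for the excess (17.5 % against 4.77 %), since the eds1-2 allele is known to come from the Landsberg erecta strain and its segment would carry other alleles whose reads may map poorly to TAIR10. Loss of EDS1 remains open for the genes outside the window and was not ruled out for those within it.

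For the comparisons of 2 groups there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split alone reached its count for Col-0 at 8 h (10487, highest other 2197) and 24 h (7832, 4749), t3 at 0 h (61, 1) and 8 h (14, 0), tpr1 at 0 h (449, 6) and 8 h (23, 0), eds1-2 at 0, 8 and 24 h (483, 3; 7658, 2408; 6670, 1680) and t3 against tpr1 at 8 h (45, 0) and 24 h (47, 1): 1 of 10 splits each. As many genes came from 3 of 10 splits for t3 at 24 h (21, highest other 537), 4 of 10 for tpr1 at 24 h (32, 2328) and 2 of 10 for t3 against tpr1 at 0 h (270, 585). Splits with many times the real count at 24 h point to structure among these libraries. For the EDS1-dependent genes at 24 h, 3 of 10 splits gave a mean as far from 0 as in t3 (0.314, highest other 0.407) and 5 of 10 as in tpr1 (0.266, 0.449).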

How the results depend on the processing

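Scaling by total counts, the Benjamini-Yekutieli adjustment, leaving out the Col-0 libraries numbered 2, leaving out libraries for the list tests, the EDS1-dependent set and the shared effects, and the estimated correlation for the EDS1-dependent set were chosen only after the results were seen. Named genes that passed in the reported or the alternative analysis kept their direction under every alternative run for them. For those that passed in neither, changes of direction were not counted. Of 1304 values each, 1298 kept their side of the threshold with DESeq2's size factors, 1266 with total counts, 1285 with DESeq2, 1211 with limma-voom, 1302 without a filter, 1291 with a replicate block, 1266 with lane and 1095 with the Benjamini-Yekutieli adjustment. Of 1292 each, 1287 did so with a 5 CPM filter and 1074 with the compared groups alone. Without the Col-0 libraries numbered 2, 1049 of 1127 did so, and with 1 library left out 9053 of 9846. All counts of changed genes stayed within 1.5 times the reported value with DESeq2's size factors, total counts and no filter. The median of all genes moved by 0.108 with DESeq2's size factors for the 24 h difference of eds1-2 (1328 higher and 638 lower, 67.5 % higher in place of 54.1 %) and by up to 0.225 with total counts (Col-0 at 8 h, 7684 higher and 3198 lower, 70.6 % in place of 57.5 %), so shares of rises depend on scaling. For eds1-2 at 24 h the share of rises went from 42.9 to 49.4 % with DESeq2's size factors. Although the totals stayed close, total counts gave 13 higher and 68 lower for t3 at 0 h (16 % higher in place of 37.7 %, median moved by -0.143) and 25 and 574 for eds1-2 at 0 h (4.17 % in place of 11.4 %, -0.16). For differences in change to 24 h they gave 163 and 34 in tpr1 and 1235 and 460 in eds1-2. The alternative pseudocounts were not run, since counts were analysed. In the simulated data 58 of 100 changes at a log2 of 1 were found. Neither depth nor spread was varied there, so this does not show which of them limited detection. Where no cause is stated below, the cause was not tested.

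The Benjamini-Yekutieli adjustment, stricter by construction, gave 6710 and 3321 genes for Col-0 at 8 and 24 h, 13 and 10 for t3 at 0 and 24 h, 34 and 19 for tpr1 at 0 and 24 h, and 184, 4061 and 3655 for eds1-2 at 0, 8 and 24 h. It gave 59 and 28 for t3 against tpr1 at 0 and 8 h, and for differences in change 0 and 0 in tpr1 and 296 and 523 in eds1-2 at 8 and 24 h. With the compared groups alone in the model, which leaves fewer libraries for the spread, counts were 1217 for Col-0 at 24 h, 18, 8 and 2 for t3, 4, 6 and 2 for tpr1, 236 and 2352 for eds1-2 at 0 and 24 h and 39, 151 and 15 for t3 against tpr1. The differences in change then numbered 1 (t3, 8 h), 0 and 0 (tpr1) and 924 and 680 (eds1-2). DESeq2 gave 289, 27 and 200 for t3, 869, 40 and 97 for tpr1, 734 for eds1-2 at 0 h and 564, 109 and 71 for t3 against tpr1, with 8 and 153 differences in change for t3 and 61 and 1168 for tpr1. In simulated data it made 23 false calls of 178 against 11 of 159 by edgeR. limma-voom gave 24 for t3 at 8 h, 160 for tpr1 at 0 h, 311 for eds1-2 at 0 h, 79 for t3 against tpr1 at 8 h and 0 and 31 differences in change for tpr1 (1337 and 3948 at an unadjusted p under 0.05). With lane as a covariate t3 at 0 h had 97, tpr1 at 0 h 290, and differences in change in tpr1 1 and 786. At least 5 CPM in 3 libraries gave 15 and 18 for tpr1 at 8 and 24 h, 31 for t3 against tpr1 at 24 h and 1 difference in change for tpr1 at 8 h. The replicate block gave 1 for that difference, and 81 and 498 for t3 and eds1-2 at 0 h.

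Without the Col-0 libraries numbered 2, t3 at 24 h had 12 genes, tpr1 at 0 h 267, and differences in change numbered 1 (t3, 24 h), 3 and 0 (tpr1) and 4564 (eds1-2, 8 h). The mean of the EDS1-dependent genes in tpr1 was 0.014 (p = 0.0879), the shared effects of t3 and tpr1 had a correlation of 0.515 and a covariance of 0.15, and those of t3 and eds1-2 changed sign to 0.113 and 0.088. Of the list tests 183 passed in place of 185, and 12 that passed before or after changed direction (adjusted p before and after). These were, in t3 at 8 h, photosynthesis (0.338, 0.00373) and glucosinolates (0.714, 0.0366). In tpr1 they were salicylic acid (0.735, 0.0463), photosynthesis (0.0993, 0.016) and chlorophyll (0.624, 0.0213) at 8 h and jasmonate synthesis (0.0242, 0.552) and response (0.0179, 0.248) at 24 h. Among differences in change they were photosynthesis in t3 at 8 h (0.000609, 0.95), jasmonate response in t3 at 24 h (0.0421, 0.0922), photosynthesis in tpr1 at 8 h (0.00147, 0.879), jasmonate synthesis in tpr1 at 24 h (0.854, 0.00175) and photosynthesis in eds1-2 at 24 h (0.168, 0.0487). With an estimated correlation 2 of 440 list tests passed, and the EDS1-dependent set did not (mean 0.314, p = 0.172 in t3; 0.266, p = 0.158 in tpr1). Its mean was 0.269 and 0.390 in t3 and 0.234 and 0.318 in tpr1 with cutoffs of a log2 of 0 and -2. Over genes with a mean log2 CPM of at least 2, correlation and covariance were 0.761 and 0.145 for t3 with tpr1, against 0.688 (0.673 to 0.701) and 0.113 (0.109 to 0.117) in simulations that share only Col-0. The correlation exceeded the simulated range here but not over all genes. That range is too narrow to decide on a shared effect, because the simulations drew each gene independently. For t3 with eds1-2 they were -0.09 and -0.045, against 0.687 and 0.113 in simulations that leave eds1-2 unchanged from Col-0.

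Leaving out 1 library at a time gave 8192 to 11152 genes for Col-0 at 8 h, 3900 to 10441 at 24 h, 14 to 192, 8 to 12 and 10 to 1324 for t3 at 0, 8 and 24 h, 51 to 752, 17 to 22 and 19 to 473 for tpr1, and 209 to 568, 4973 to 8917 and 5119 to 7260 for eds1-2. For t3 against tpr1 it gave 89 to 382, 32 to 39 and 31 to 45. Differences in change ranged over 0 to 3 and 0 to 714 (t3), 0 to 28 and 0 to 2267 (tpr1) and 748 to 3634 and 1136 to 2382 (eds1-2). List tests past the threshold ranged from 175 to 204 with each Col-0 library left out (mutant libraries were not left out for these tests), and the EDS1-dependent mean from 0.071 to 0.534 in t3 and from 0.02 to 0.486 in tpr1. For t3 with tpr1 the correlation ranged from 0.515 to 0.762, the covariance from 0.15 to 0.449 and the shared calls from 2 to 352. For t3 with eds1-2 they ranged from -0.062 to 0.114, from -0.056 to 0.111 and from 1 to 239. The highest counts for t3 and tpr1 at 24 h, the highest EDS1-dependent means and the highest shared calls (352 and 239) came without Col-0 replicate 3 at 24 h, and the lowest EDS1-dependent means without Col-0 replicate 2 at 24 h.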

Other observations

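The tests on genes that changed at every time were chosen only after the results were seen. In t3, 11 genes changed at 0, 8 and 24 h, in tpr1 16 and in eds1-2 382, and 3 were shared by t3 and tpr1 (PTAC17, AT2G01422 and QQS), the last 2 of them with eds1-2 as well. QQS was higher in t3 (3.27, 3.16 and 2.72) and tpr1 (2.99, 3.38 and 2.68) but lower in eds1-2 (-3.54, -3.54 and -5.59). Besides TPL, TPR4, TPR2 and TPR3, the 11 in t3 included AT1G34440 (log2 6.12, 8.25 and 6.96), AT2G05350 (7.19, 6.42 and 6.80) and AT5G35935 (8.15, 8.48 and 7.55), chosen after their values were seen. In tpr1, LBD26 (-2.64, -2.97 and -4.12), BSK6 (-1.46, -2.07 and -2.16) and MRU1 (-2.72, -2.45 and -3.16), also chosen after their values were seen, were lower at each time, and MRU1 lies beside AT5G35480 on chromosome 5. Of the 16 genes in tpr1, 1 lay within 3 Mb of TPR1 (PTAC17; Fisher's exact test, two-sided, p = 0.46), and of the 11 in t3, 1, 1 and 2 lay near TPR1, TPL and TPR4 (exact p = 0.346, 0.528 and 0.16). Such stretches were therefore not detectable with so few genes. AT2G01422 was almost unread in all 3 mutants and read in Col-0 throughout (815, 2760 and 1048 reads at 0, 8 and 24 h).

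At 0 h some salicylic acid genes were lower in each mutant: 2 of 20 in t3, 5 in tpr1 and 13 in eds1-2. With an estimated correlation the list passed in eds1-2 (adjusted p = 0.0153) but not in t3 (0.15) or tpr1 (0.177). ICS1 was lower in tpr1 (-1.49) and t3 (-1.75), CBP60g in t3 (-2.72), and WRKY54 and SARD1 in eds1-2 (-3.87 and -3.96). Of 449 genes changed in tpr1 and 483 in eds1-2 at 0 h, 203 were the same genes, 202 of them in the same direction. These comparisons share the Col-0 libraries at 0 h. Of those, replicates 1 and 2 lay at -74.6 and -64.3 on principal component 1. The mutant libraries at 0 h ranged from -143.8 (eds1-2 replicate 2) to -105.7 (t3 replicate 2), and Col-0 replicate 3, at -112.9, lay among them. The lower salicylic acid genes in the mutants may thus partly reflect Col-0 replicates 1 and 2, which was not tested. Those replicates were on lane 4 and Col-0 replicate 3 was on lane 3. Of the mutant libraries at 0 h only eds1-2 replicate 1 (-116.5 on component 1) was on lane 4, so lane and genotype are partly confounded. The count in tpr1 became 92, 69 and 752 without Col-0 replicates 1, 2 and 3 and 246 and 51 without tpr1 replicates 1 and 2, and in eds1-2 292 and 252 without Col-0 replicates 1 and 2 and 209 and 274 without eds1-2 replicates 2 and 3. Whether the overlap goes beyond the shared libraries was not tested at 0 h.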
